A study of Sus scrofa with 6 samples.

How the data were processed

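RNA levels were measured in primary cultures of mesenchymal stem cells, the adherent stromal cells of bone marrow, from female American Yorkshire pigs aged 4 months. Of 6 cultures, all at passage 0, 3 came from marrow of the mandibular symphysis, the midline of the lower jaw, and 3 from marrow of the tibia. The design text gives 3 pigs as the source of both kinds of marrow. The labels number the samples 1 to 3 within each site and call them biological replicates, but they do not say that a number marks a pig. Mandibular and tibial samples were therefore treated as unpaired, and a fit with the number as a block was an alternative. Arrays from the same pig are not fully independent of each other, which the unpaired tests do not take into account. Per the labels' protocols, unfractionated marrow was plated on plastic, so no sorting or gating removed other adherent cells before RNA was taken. Labelling used the WT Terminal Labeling Kit, per the labels' protocols.

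The deposited values are log2 levels for 27558 probe sets on each of the 6 arrays. Per the submitters' processing notes, the authors used RMA, Affymetrix Expression Console and Transcriptome Analysis Console 3.0. RMA corrects background, makes the distributions of the arrays equal and summarises probes, so levels are relative and a shift shared by all genes of an array would have been removed. The settings, the genome build and the probe annotation are not given in the sources used here, and no coordinates are given for that reason. The values ranged from 1.10 to 14.26, with array medians between 5.63 and 5.71. The deposited values carry no measure of detection above background, so low levels cannot be separated from background. The precision of each value is limited by the number of arrays.

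Gene names came from GEO's platform annotation. It gave exactly 1 symbol for 13157 probe sets, several for 523 and none for 13878. Of the symbols, 7 were updated through the Entrez gene number. After placeholder symbols were set aside, 11689 probe sets named 10871 genes, and the probe set with the highest mean over the 6 arrays stood for each gene. A probe set without a symbol is unnamed here and may still measure a gene. No list of control probes was used, so all 27558 probe sets were tested. Of these, 637 repeated the values of another probe set exactly.

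Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust fitting), two-sided, with Benjamini-Hochberg adjustment over all 27558 probe sets and a threshold of 0.05. Each difference is mandibular minus tibial on the log2 scale, with its standard error (SE) from limma. Levels of a gene or list are given as mean ± SD over 3 arrays.

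Before the data were examined, 37 gene lists were written down. Those for position were HOX genes, limb identity, jaw and cranial patterning, and neural crest specifiers. Those for skeletal and stromal lineages were stromal cell markers, osteoblast, osteoclastogenic signals, adipocyte, chondrocyte and tendon. Those for other cells that marrow plating can carry over were macrophage and monocyte, osteoclast, granulocyte, lymphocyte, erythroid and megakaryocyte, endothelial, smooth muscle and pericyte, skeletal muscle, epithelial, and Schwann and neural cells. Those for programs were cell cycle, senescence, collagens and matrix, matrix proteases, interferon response, antigen presentation, cytokines and chemokines, angiogenesis, hypoxia and glycolysis, cholesterol synthesis, BMP and TGFB signalling, WNT signalling, and a joint list of FGF, IGF, hedgehog and retinoic acid signalling. Those for RNA quality were immediate early and heat shock, ribosomal protein, mitochondrial respiration and housekeeping genes. All 37 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and limma's fry were run beside it. The mean level of each list was also compared between sites with a two-sided exact permutation test, which cannot give a p below 0.1 for 3 arrays against 3.

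The genes named were also chosen by a rule set before the data were examined. In each direction it takes 10 genes with no overlap between the 3 and 3 values. Those past the adjusted threshold come first, by largest difference. Where fewer than 10 pass, the places left are filled by smallest unadjusted p, also only from genes without overlap. In each list it takes up to 4 members with the smallest unadjusted p. It always takes RUNX2, SPP1, PPARG, SOX9, THY1, NT5E, ENG, CD44, PTPRC and CD34. For RUNX2 no probe set with a single symbol was found in the annotation, and it is not analysed here. Any other gene named is said to have been chosen after its values were seen.

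The fit and the list test were tested on simulated data that used the means and residual spread of these 27558 probe sets, with independent noise. In 20 runs with 200 probe sets changed, 47.8% of changes of 1 log2 unit were called, 85.9% of changes of 2 units and 96.3% of changes of 4 units. The simulated changes followed the labelled sites on every array, so these shares do not hold where an array goes against its label. In 20 runs without any change there were 0 calls, and 5.24% of probe sets lay at an unadjusted p under 0.05. A list shifted by 1 log2 unit was called in 20 of 20 runs. Lists that were not shifted, antigen presentation left aside, gave 2 calls over these runs. With independent noise the runs do not show how the preset correlation performs where genes move together. The correlation estimated from the real data was 0.704 for macrophage, 0.954 for cell cycle and 0.794 for interferon genes.

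The alternatives set before the data were examined were the replicate number as a fixed or random block, centring of each array on its median, a further quantile normalization, removal of probe sets of low level under either of 2 limits, array weights, only named genes, eBayes with trend and robust fitting, an unmoderated fit, other thresholds, the mean of all probe sets of a gene, the other list tests, and leaving out each array in turn. Added after the data were seen were the mean of the macrophage and monocyte list as a covariate, and a fit without the arrays labelled mandibular 2 and tibial 3.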

Results

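Genome-wide RNA levels were compared between mesenchymal stem cells grown from porcine mandibular marrow and those grown from tibial marrow. The study asked how stromal cells of the jaw and of a long bone differ in expression. There were 6 arrays, 3 for each site, from cultures at passage 0 grown to 80% confluence. Per the design text, marrow of both sites came from 3 pigs, while no label ties a sample number to a pig. The jaw skeleton derives from cranial neural crest and the tibia from mesoderm, and the lists of positional genes tested here address that difference. Array medians lay between 5.63 and 5.71 on the log2 scale, and the number of arrays limits the precision of every comparison.

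The arrays did not separate by labelled site. The mean correlation over all probe sets was 0.9794 between arrays of the same site and 0.9787 between arrays of different sites, with a range from 0.963 to 0.9913. The first principal component held 49.6% of the variance. On it, the arrays labelled mandibular 1, mandibular 3 and tibial 3 scored -26.1, -39.3 and -35.5, and the arrays labelled mandibular 2, tibial 2 and tibial 1 scored 10.4, 28.8 and 61.7. The highest correlation of any pair, 0.9913, was between the arrays labelled mandibular 3 and tibial 3.

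**Figure D1:**
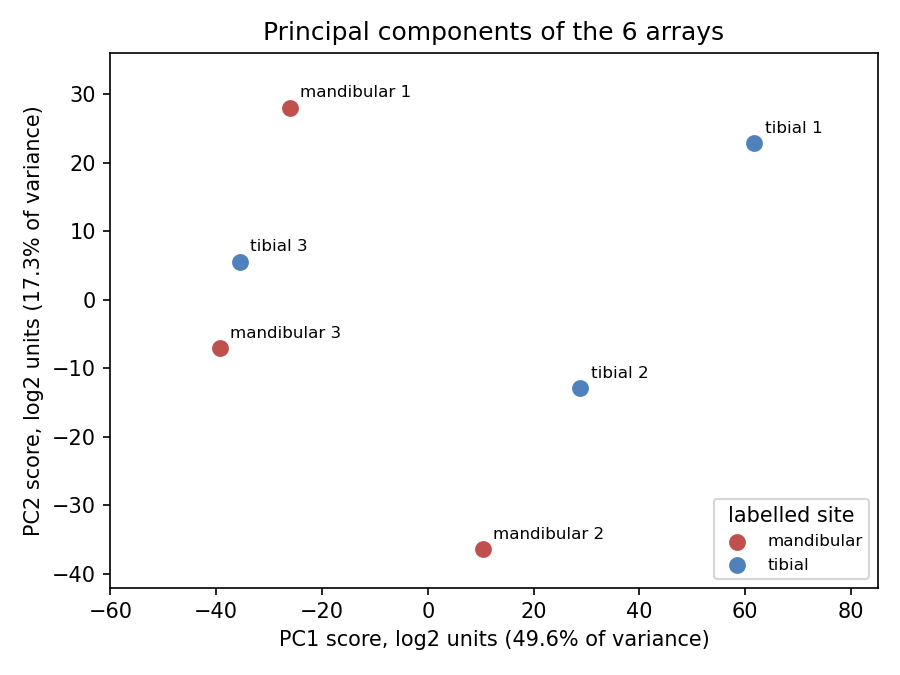
Scores of the 6 arrays on principal components 1 (x axis, 49.6% of the variance) and 2 (y axis, 17.3%), in log2 units, coloured by labelled site with 1 point per array. The array labelled tibial 3 scores -35.5 on component 1, beside mandibular 3 at -39.3, and the array labelled mandibular 2 scores 10.4, on the side of tibial 1 and tibial 2.

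No gene passed the test between the labelled sites. With limma, 0 of 27558 probe sets passed the adjusted threshold, and the smallest adjusted p was 0.9995. At an unadjusted p under 0.05 there were 836 probe sets, 3.03% of all where chance gives 5%, of which 371 were higher in mandibular and 465 in tibial cultures. The 3 mandibular and 3 tibial values did not overlap for 1907 probe sets, 6.92% where chance gives 10%. The unmoderated fit also gave 0 calls, with 848 probe sets at an unadjusted p under 0.05. Without the array labelled tibial 3, limma gave 2 calls and 2070 probe sets at an unadjusted p under 0.05, and without tibial 1 it gave 1 call. With the arrays labelled mandibular 2 and tibial 3 both left out, it gave 195 calls, a fit chosen after the data were seen. A difference between sites can be missed where an array goes against its label, so 0 calls do not show that such differences are absent.

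In each direction, 10 genes were taken by smallest p among those without overlap between the values of the sites. Their separation was thus a condition of the choice, and none passed the adjusted threshold (adjusted p = 0.9995 for each in limma). Among those with higher mandibular levels, TRPA1, a cation channel that senses irritants, had the largest difference, 1.73 (SE 0.34), or 3.33-fold, with a level of 6.19 ± 0.63 (SD, n = 3) against 4.46 ± 0.38 (SD, n = 3). The kinesin motor gene KIF21A, which had the smallest p of these genes, differed by 0.84 (SE 0.11). The adhesion molecule gene DSCAML1 differed by 0.76 (SE 0.14) and the transcription factor gene ETV1 by 0.73 (SE 0.16). BMP4, a bone morphogenetic protein, differed by 0.78 (SE 0.19) and PLXNA2, a semaphorin receptor gene, by 0.66 (SE 0.16). The differences of LGI3, CPNE4, TESMIN and TTC7A were 0.97, 0.89, 0.51 and 0.51. Among those with higher tibial levels, LAMA2, which encodes a laminin chain of basement membranes, differed by -1.71 (SE 0.39), with 5.03 ± 0.08 (SD, n = 3) in mandibular against 6.75 ± 0.84 (SD, n = 3) in tibial cultures. NAAA, a lysosomal amidase gene, differed by -1.35 (SE 0.30). CPED1 differed by -1.03 (SE 0.16) and RGS2, a regulator of G protein signalling, by -1.01 (SE 0.18). IL10RA, a chain of the interleukin-10 receptor, differed by -0.81 (SE 0.18). The differences of DOCK10, SUCLA2, MIRLET7C, BCAR3 and MAG were -0.87, -0.70, -0.58, -0.58 and -0.47. Some levels were low, where lower quartiles of the arrays lay between 3.855 and 3.941. In mandibular against tibial cultures MIRLET7C measured 2.22 against 2.80, TESMIN 3.97 against 3.46, CPNE4 4.52 against 3.62 and DOCK10 3.89 against 4.76. Such levels cannot be separated from background.

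Genes of macrophages and monocytes had lower levels in the cultures labelled mandibular. Of 24 measured members, 23 were lower, and the median difference was -2.14, or 4.40-fold (camera adjusted p = 8.92e-15 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.703) and with fry (adjusted p = 0.793), and the exact permutation test of the list means gave p = 0.2. The list mean was 5.47 ± 0.70 (SD, n = 3) in mandibular and 7.28 ± 1.53 (SD, n = 3) in tibial cultures. SPI1, the master transcription factor of myeloid cells, differed by -1.96 (SE 0.69), the mannose receptor gene MRC1 by -2.25 (SE 0.86), the lipopolysaccharide co-receptor gene CD14 by -0.77 (SE 0.29) and the integrin gene ITGAM by -0.33 (SE 0.12). The list means were 8.46 and 7.83 on the arrays labelled tibial 1 and tibial 2, 6.28 on mandibular 2, 5.55 on tibial 3, and 5.07 and 5.06 on mandibular 1 and mandibular 3. Without the array labelled tibial 3 the median was -3.23.

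Lists of granulocyte, antigen presentation, osteoclast and adipocyte genes also passed with the preset correlation, and none of these calls held with an estimated correlation (adjusted p = 0.703 for each) or with fry (adjusted p = 0.793 for each). The granulocyte list was lower in mandibular cultures in 8 of 8 members, with a median of -0.32 (camera adjusted p = 0.00193), and its list mean was highest on the arrays labelled tibial 1 and tibial 2, at 5.37 and 5.25. Before adjustment its p was 0.0242 in camera with an estimated correlation, which was 0.0324, and 0.033 in fry. The exact permutation test of its list means gave p = 0.1, the smallest possible. Its members included S100A12 at -1.96 (SE 0.83), S100A8 at -0.37 (SE 0.16), both calcium-binding proteins of neutrophils, and LCN2 at -1.28 (SE 0.61). In mandibular against tibial cultures S100A8 measured 3.12 against 3.50, S100A12 3.54 against 5.49 and LCN2 7.94 against 9.22. Levels as low as those of S100A8, and of S100A12 in mandibular cultures, cannot be separated from background. The antigen presentation list was lower in 13 of 18 members, with a median of -0.28 (camera adjusted p = 0.0114). Its leading members were the class II genes SLA-DRA, at -3.24 (SE 1.34), SLA-DQA1, at -2.65 (SE 0.98), SLA-DQB1, at -1.80 (SE 0.67), and SLA-DOB, at -0.78 (SE 0.25). The osteoclast list was lower in 10 of 13 members, with a median of -0.25 (camera adjusted p = 0.0429). ACP5, the acid phosphatase used to stain osteoclasts, differed by -2.41 (SE 0.90), MMP9 by -2.88 (SE 1.26) and the proton pump subunit gene ATP6V0D2 by -2.38 (SE 1.09). The adipocyte list was lower in 19 of 23 members, with a median of -0.15 (camera adjusted p = 0.013). Its members included CD36, a fatty acid transporter gene also used by macrophages, at -3.22 (SE 1.55), APOE at -1.46 (SE 0.70), SCD at -0.52 (SE 0.22) and LIPE at 0.37 (SE 0.15). Without tibial 1 CD36 and APOE differed by -1.58 and -0.66, and without tibial 3 CD36 differed by -4.88. The list means of antigen presentation, osteoclast and adipocyte genes were likewise highest on the arrays labelled tibial 1 and tibial 2. The osteoclast call in the preset test was lost without mandibular 1, mandibular 3, tibial 1 or tibial 2, the antigen presentation call without mandibular 1, mandibular 3 or tibial 1, and the adipocyte call without mandibular 3 or tibial 1. The milder filter on low levels and array weights also ended the osteoclast call. Without tibial 1 the medians were -0.04 for osteoclast and -0.15 for antigen presentation genes, and without tibial 3 they were -0.42 for osteoclast and -0.27 for adipocyte genes. The granulocyte median was -0.16 without tibial 2, still called.

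Cell cycle genes had higher levels in the cultures labelled mandibular. All 25 measured members were higher, with a median of 0.96, or 1.94-fold (camera adjusted p = 1.71e-11 with the preset correlation). The call was lost with an estimated correlation (adjusted p = 0.703) and with fry (adjusted p = 0.793), and the exact permutation test of the list means gave p = 0.3. The spindle gene TPX2 differed by 1.22 (SE 0.57), the transcription factor gene MYBL2 by 1.08 (SE 0.50), the cytokinesis gene ANLN by 1.06 (SE 0.51) and the kinetochore gene CENPF by 1.00 (SE 0.48). The list mean was 7.58 ± 0.50 (SD, n = 3) in mandibular and 6.68 ± 1.01 (SD, n = 3) in tibial cultures. It was lowest on the arrays labelled tibial 1 and tibial 2, at 5.85 and 6.39, the arrays with the highest macrophage list means, and it was 7.81 on tibial 3. The median was 0.50 without tibial 1, 0.57 without mandibular 3 and 1.59 without tibial 3.

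The interferon response list was higher in 21 of 24 members in mandibular cultures, with a median of 0.39 (camera adjusted p = 0.0223), and this rested on the array labelled mandibular 2. The call was lost with an estimated correlation (adjusted p = 0.703) and with fry (adjusted p = 0.793), and the exact permutation test of the list means gave p = 0.9. The list mean was 7.78 on that array and between 5.52 and 6.21 on the other 5 arrays. The viral RNA sensor gene IFIH1 differed by 0.75 (SE 0.42), IFIT1 by 1.34 (SE 0.89), USP18 by 0.57 (SE 0.42) and OASL by -0.34 (SE 0.20). Without the array labelled mandibular 2 the direction turned, with a median of -0.09 (camera adjusted p = 0.0352). Without tibial 3 the median was 0.19 and the call was lost, as it was with array weights. The median was 0.93 without mandibular 3, 0.69 without mandibular 1 and 0.62 without tibial 1, called in each.

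**Figure D2:**
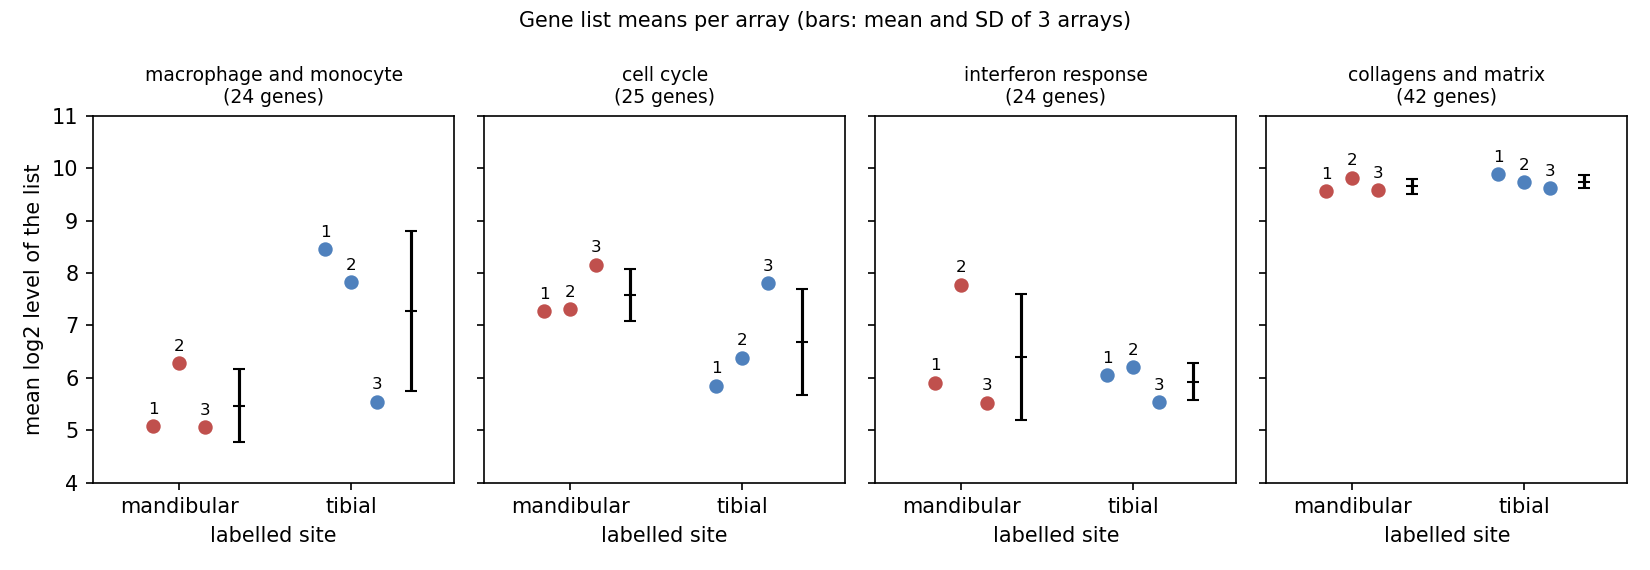
Mean log2 level (y axis) of 4 gene lists on each array (points, numbered by replicate) by labelled site (x axis), with the mean and SD of 3 arrays as bars. Macrophage and monocyte genes are highest on tibial 1 and tibial 2, at 8.46 and 7.83, where cell cycle genes are lowest, interferon genes are high on mandibular 2, at 7.78, and collagen and matrix genes stay between 9.56 and 9.89.

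Of the positional genes, 8 of 27 HOX and 15 of 28 jaw list genes had a range of at least 1 log2 unit over the arrays, and none of their lists passed between the labelled sites. HOX genes, which set identity along the trunk and limbs and are off in the cranial neural crest that forms the jaw, were lower in mandibular cultures in 19 of 27 members. Their median was -0.15 (camera adjusted p = 0.146), and 0 members were called adjusted over the list alone. By the rule, the members named are HOXB7 at 0.38 (SE 0.12), HOXA2 at -0.43 (SE 0.18), HOXA4 at -0.30 (SE 0.19) and HOXA11 at -0.70 (SE 0.45). HOXB7 measured 3.86 in mandibular and 3.47 in tibial cultures, low levels that cannot be separated from background. The jaw and cranial patterning list had a median of 0.14, with 18 of 28 members higher (camera adjusted p = 0.527). Its named members are DLX3 at 0.66 (SE 0.31), TWIST1 at -0.46 (SE 0.24), BARX2 at -0.20 (SE 0.12) and TBX22 at -0.21 (SE 0.14). Limb identity genes had a median of 0.09 (camera adjusted p = 0.448), with TBX3 at 1.17 (SE 0.67). Neural crest specifiers had a median of 0.12 and a mean of -0.04, with the test on the higher side (camera adjusted p = 0.448), and included TFAP2A at 1.29 (SE 0.60) and the endothelin receptor gene EDNRB at -2.91 (SE 1.44). Without tibial 1 TFAP2A and EDNRB differed by 0.78 and -1.53, and without tibial 3 by 2.00 and -4.52. Without the array labelled mandibular 2 the HOX list passed, with a median of -0.18 (camera adjusted p = 0.000596), and without tibial 3 it passed with -0.25 (camera adjusted p = 0.0181). It also passed under the milder filter on low levels, with -0.16 (camera adjusted p = 0.0362). These calls are at the preset correlation, and with all 6 arrays the HOX list had adjusted p = 0.703 with an estimated correlation, which was not run for these fits. In single omissions the jaw median ranged from 0.03 (without tibial 2) to 0.13, the limb median from 0.03 (without tibial 3) to 0.17 and the neural crest median from -0.06 (without mandibular 2) to 0.14.

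The levels on single arrays show where the spread of these genes lay, for genes chosen after their values were seen. ALX1, a homeobox gene of the craniofacial mesenchyme, measured 8.08, 7.44 and 7.97 on the arrays labelled mandibular 1, mandibular 3 and tibial 3, and 3.86, 3.90 and 3.54 on those labelled mandibular 2, tibial 1 and tibial 2. LHX8, a LIM homeobox gene of the jaw primordia, measured 8.26, 8.25 and 8.67 on the first set of arrays and 3.70, 4.77 and 4.10 on the second. PAX9, HAND2 and MSX1 were arranged in the same way. HOXA7 measured 5.26, 5.23 and 5.89 on mandibular 1, mandibular 3 and tibial 3, and 8.40, 8.01 and 7.92 on mandibular 2, tibial 1 and tibial 2. HOXA9 measured 4.41, 4.35 and 5.10 against 6.97, 6.67 and 7.38, and HOXD10 measured 4.41, 4.56 and 4.85 against 6.26, 6.74 and 6.53. Not every jaw list gene was arranged so. BARX1 and EDN1 had their highest levels, 7.45 and 8.30, on mandibular 2. Of 23 HOX and jaw list genes with a range of at least 1 log2 unit, the level on the array labelled mandibular 2 lay nearer the tibial median than the mean of mandibular 1 and 3 for 18. These 18 include every HOX gene among the 23. They also include the jaw list genes BARX1, EDN1 and DLX4, whose level on mandibular 2 was above every tibial level. For the jaw list genes DLX1, DLX2, DLX3, OSR2 and TWIST1 the level on mandibular 2 lay nearer the mean of mandibular 1 and 3. On the array labelled tibial 3 the level lay nearer the mandibular median than the mean of tibial 1 and 2 for 23. On each of the other 4 arrays the level lay nearer the other site for 3 to 6 of the 23 genes.

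**Figure D3:**
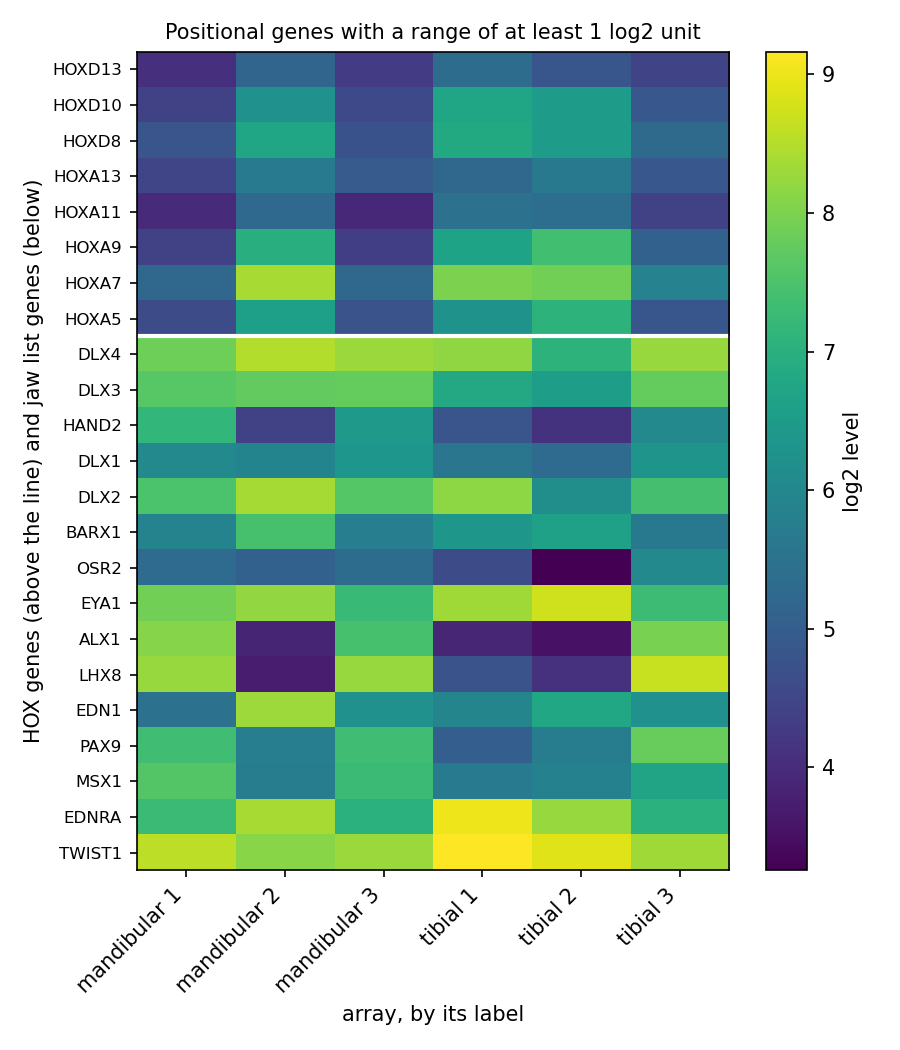
Log2 level (colour) of 23 genes, HOX genes above the line and jaw list genes below it, with a range of at least 1 log2 unit (rows) on each array by its label (columns). ALX1 and LHX8 are low on mandibular 2, at 3.86 and 3.70, and high on tibial 3, at 7.97 and 8.67, while HOXA7 is high on mandibular 2, at 8.40, and low on tibial 3, at 5.89.

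Of the genes fixed for naming, none passed between the labelled sites. THY1 measured 10.61 ± 0.10 (SD, n = 3) in mandibular and 10.63 ± 0.01 (SD, n = 3) in tibial cultures, and its difference of -0.01 (SE 0.11) turned to 0.01 when each array was centred on its median. ENG measured 10.38 ± 0.31 (SD, n = 3) and 9.86 ± 0.36 (SD, n = 3), a difference of 0.52 (SE 0.23). NT5E differed by -0.47 (SE 0.50) and CD44 by 0.52 (SE 0.44). In single omissions NT5E ranged from -0.87 to -0.04 and CD44 from 0.15 to 0.99. The haematopoietic stem cell and endothelial marker CD34 measured 4.80 ± 0.32 (SD, n = 3) and 4.96 ± 0.16 (SD, n = 3). PTPRC, the pan-leukocyte antigen CD45, measured 4.00 ± 0.76 (SD, n = 3) in mandibular and 6.18 ± 1.99 (SD, n = 3) in tibial cultures, a difference of -2.18 (SE 0.96). SPP1 differed by -0.17 (SE 0.77), PPARG by -0.72 (SE 0.75) and SOX9 by 0.30 (SE 0.36). Without tibial 1 these were 0.50, -0.22 and 0.05, without tibial 3 SPP1 and PPARG were -0.95 and -1.63, and without tibial 2 SOX9 was 0.68. The adjusted p in limma was 0.9995 for each of these genes. The list of stromal markers had a median of -0.07 (camera adjusted p = 0.537), with the adhesion molecule gene VCAM1 at -2.55 (SE 1.31) and the chemokine gene CXCL12 at -0.40 (SE 0.21).

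The skeletal lineage lists did not pass the test between sites. Osteoblast genes had a median of -0.03 (camera adjusted p = 0.697), with BMP4 at 0.78, DLX3 at 0.66, PHEX at -0.50 (SE 0.22) and ANKH at -0.96 (SE 0.51). Chondrocyte genes had a median of 0.01 (camera adjusted p = 0.97), with the matrix genes CHAD at 1.23 (SE 0.41) and HAPLN1 at 0.80 (SE 0.30), and with CNMD at -0.37 (SE 0.19) and COL2A1 at -0.22 (SE 0.12). Tendon and ligament genes had a median of -0.04 (camera adjusted p = 0.753), with DCN at -0.71 (SE 0.46) and TNC at 0.42 (SE 0.42). Osteoclastogenic signals had a median of 0.06 (camera adjusted p = 0.448), with the axon guidance gene SEMA3A at 0.86 (SE 0.39).

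Of the other cell types, lymphocyte genes had a median of -0.07 (camera adjusted p = 0.146), with NKG7 at -2.54 (SE 1.00). Endothelial genes had a median of -0.08 (camera adjusted p = 0.294), with PECAM1 at -0.55 (SE 0.16) and ESAM at -0.54 (SE 0.18), and KDR at 0.45 (SE 0.19). Smooth muscle and pericyte genes had a median of -0.06 (camera adjusted p = 0.753), with SMTN at 0.35 (SE 0.10) and KCNJ8 at -0.48 (SE 0.26). Skeletal muscle genes had a median of 0.11 (camera adjusted p = 0.294) and Schwann and neural genes 0.10 (camera adjusted p = 0.294). Epithelial genes had a median of -0.09 (camera adjusted p = 0.146). Erythroid and megakaryocyte genes had a median of 0.05 and a mean of -0.02, with the test on the higher side (camera adjusted p = 0.906). Some of these lists passed in single alternatives. Smooth muscle and pericyte genes did so without mandibular 2, at -0.21, and skeletal muscle genes without tibial 1, at 0.22. Epithelial genes did so without mandibular 1 or tibial 2, at -0.11 in each, and lymphocyte genes under the milder filter on low levels, at -0.11. With all 6 arrays these 4 lists had an adjusted p of 0.703 with an estimated correlation, or 0.958 for smooth muscle and pericyte genes, which was not run for these fits.

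Matrix and signalling lists also stayed short of the threshold. Collagen and matrix genes had a median of -0.08 (camera adjusted p = 0.16), with COL12A1 at -0.57 (SE 0.29) and FBLN5 at 0.46 (SE 0.34), and matrix proteases and their inhibitors had -0.07 (camera adjusted p = 0.448), with MMP1 at 0.78 (SE 0.31) and ADAMTS12 at -0.29 (SE 0.12). BMP and TGFB signalling genes had a median of 0.07 (camera adjusted p = 0.207), with the BMP antagonist gene NOG at 1.20 (SE 0.43), the inhibitory gene SMAD6 at 0.62 (SE 0.23) and the activin antagonist gene FST at -0.32 (SE 0.18). WNT signalling genes had a median of -0.03 and a mean of 0.05, with the test on the lower side (camera adjusted p = 0.962), and included the WNT inhibitor gene WIF1 at 1.51 (SE 0.48) and LEF1 at -0.44 (SE 0.31). The joint list of FGF, IGF, hedgehog and retinoic acid signalling had a median of 0.08 (camera adjusted p = 0.16), with IGF1 at -1.31 (SE 0.52) and FGF1 at 0.40 (SE 0.17). Cytokines and chemokines had a median of -0.06 (camera adjusted p = 0.448), with CCL8 at -1.97 (SE 0.96) and PTGES at 0.55 (SE 0.20), and angiogenesis genes had 0.10 (camera adjusted p = 0.582). Hypoxia and glycolysis genes had a median of -0.11 (camera adjusted p = 0.16), cholesterol synthesis genes 0.12 (camera adjusted p = 0.178) and senescence genes 0.03 (camera adjusted p = 0.962). Without mandibular 2, medians of -0.13 for collagen and matrix, -0.29 for cytokine, -0.35 for hypoxia and 0.33 for cholesterol genes passed. Without tibial 3, those of -0.18 for collagen and matrix and -0.24 for hypoxia genes passed, and without mandibular 3 that of 0.11 for BMP and TGFB genes. These calls are at the preset correlation, and with all 6 arrays these lists had an adjusted p of 0.703 with an estimated correlation, or 0.849 for cytokines, which was not run for these fits.

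Lists that follow RNA quality and array scaling had small differences. Ribosomal protein genes had a median of 0.03 (camera adjusted p = 0.406), mitochondrial respiration genes 0.04 (camera adjusted p = 0.177), immediate early and heat shock genes 0.03 (camera adjusted p = 0.582) and housekeeping genes -0.03 (camera adjusted p = 0.527). Without mandibular 2 the ribosomal protein list passed at the preset correlation, with a median of 0.12, and with all 6 arrays its adjusted p was 0.909 with an estimated correlation. Over the 37 lists, 7 passed with the preset correlation, 0 with an estimated correlation and 0 with fry. With an estimated correlation and with fry, 1 of the 37 lists lay at an unadjusted p under 0.05, where chance gives 5%. It was the granulocyte list in both. Adjusted over the list alone, 0 members of any list passed in limma, and the smallest such adjusted p was 0.0972. Exact permutation tests of the 37 list means gave p = 0.1, the smallest possible, for the granulocyte and lymphocyte lists and larger values for the others. By chance a share of 0.1 of such tests reaches that value, so it does not set these lists apart.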

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

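The fits with the macrophage list mean as a covariate, and without both arrays labelled mandibular 2 and tibial 3, were chosen after the data were seen. With limma, no probe set passed the adjusted threshold under either replicate block, both scalings, either filter on low levels, array weights, named genes only, trend with robust fitting, the unmoderated fit, an adjusted p under 0.1, or the covariate. The count was 113 at an unadjusted p under 0.05 with at least 2-fold, a looser threshold, and 195 without mandibular 2 and tibial 3. Leaving out single arrays gave 0 to 2 calls, 1 without tibial 1 (ANXA8) and 2 without tibial 3 (AQP9 and PLPPR4), genes chosen after their values were seen. The 836 probe sets at an unadjusted p under 0.05 became 1511 with the replicate block and 1295 with a random block. They became 306 without probe sets of low level and 293 with named genes only, where fewer probe sets are tested, and 2617 without mandibular 2 and tibial 3. Single omissions gave 538 (without mandibular 3) to 2070 (without tibial 3). The replicate numbers were not taken to pair the arrays, since deviations of same-numbered arrays correlated at -0.0331, 0.212 and 0.473, not all of them positive. For 3 of 6 arrays the deviations correlated best with their own number. The deviations are from the means of the labelled sites, so an array that goes against its label shapes them too. They cannot decide against pairing for that reason, and whether a number marks a pig stays open. Of the gene lists, 7 passed in the preset test, 8 with the replicate block, which added the HOX list (median -0.15, adjusted p = 0.0393), 0 with an estimated correlation, 0 with fry, 14 without mandibular 2 and tibial 3, and 5 to 14 with single omissions, 14 without mandibular 2. The macrophage and cell cycle lists lost their calls with an estimated correlation or fry, which by construction leave the medians of -2.14 and 0.96 as they are. In single omissions each of the 37 list medians moved by over 1.5 times or turned, 15 of them turning. The macrophage median ranged from -3.23 to -1.45 and the cell cycle median from 0.50 to 1.59, and these lists stayed called in each omission. With the covariate, directions turned to 0.046 for macrophage genes, by construction, and to -0.20 for cell cycle, 0.19 for adipocyte, 0.20 for smooth muscle and pericyte, 0.14 for osteoclast, -0.0082 for antigen presentation, whose test turned, 0.31 for cytokine and -0.10 for ribosomal protein genes. The interferon median turned to -0.35 without mandibular 2 and tibial 3, and ranged from -0.092 (without mandibular 2) to 0.93 in single omissions. The cause of these changes was not tested where none is stated. Over all alternatives, 567 gene list results and 2386 named gene results kept their side of the threshold, 57 and 82 of them with a sign change that was called in neither fit, while 24 and 32 gained a call. Of the 186 genes taken by the rule or chosen after their values were seen, 131 moved by over 1.5 times or turned in at least 1 single omission, and 15 turned. A further 28 gene list results lost their call and 10 turned. No scaling moved the median of all probe sets by more than 0.1, the values being 0.0041 as deposited, 0.0292 centred and 0.00504 after quantile normalization. Signal over background could not be assessed from these values.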

Other observations

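The tests of explanations, the fits with a covariate or without both arrays, and the counts of probe sets over other splits were chosen only after the result was seen. The count of gene lists over other splits, camera with an estimated correlation and fry were not. Complement genes of the macrophage and monocyte list were high on the arrays with high means of that list, to which they contribute. C1QA, C1QB and C1QC, which encode the chains of the complement component made by tissue macrophages, were chosen after their values were seen, for their high mean array levels, which do not rank transcripts of different genes. C1QB measured 10.87 and 10.35 on the arrays labelled tibial 1 and tibial 2, 8.45 on mandibular 2, 7.04 on tibial 3, and 5.55 and 5.26 on mandibular 1 and mandibular 3. C1QA measured 10.62 and 10.33 on tibial 1 and tibial 2 and 6.74 and 6.66 on mandibular 1 and mandibular 3. CD86, another member with a high array level chosen after its values were seen, went the other way, with 9.85, 9.87 and 9.64 on mandibular 1, mandibular 3 and tibial 3 against 7.81, 8.44 and 7.44 on mandibular 2, tibial 1 and tibial 2. With mandibular 2 and tibial 3 both left out, limma called 44 probe sets higher in mandibular and 151 higher in tibial cultures. Of the 126 named genes among them, 17 belonged to the macrophage and monocyte list, whose median was then -3.64, and the cell cycle median was 1.73. That fit has 2 arrays for each site, and the arrays were left out because of their HOX and jaw gene levels, so it is no evidence on those genes. They were also the mandibular array with the highest macrophage list mean and the tibial array with the lowest, and tibial 3 had the highest cell cycle list mean of its site, so leaving them out widens these medians too.

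On the arrays labelled mandibular 2 and tibial 3, the levels of most of the 23 HOX and jaw list genes with a range of at least 1 log2 unit lay nearer the other site. HOX RNA brought by macrophage-type cells is argued against for mandibular 2, since the 8 HOX genes among them lay 0.307 above the tibial median on mandibular 2 (median absolute deviation 0.14), and all 27 measured HOX genes lay 0.0556 above it (0.353), while macrophage genes lay at -1.84 (0.504); it stays open for tibial 3, where HOX genes lay at -1.58 (0.62) and macrophage genes at -3.17 (1.53) against tibial 1 and 2. For the 5 jaw genes lower there by over 1 log2 unit, picked for that fall, fewer stromal cells are also argued against, since collagen and matrix genes lay 0.108 above mandibular 1 and 3 in the median (median absolute deviation 0.661) and the smallest of the 5 falls was -1.57, but over all 15 variable jaw genes the median was -0.248 (1.96), not separated from that of matrix genes. The count of these genes nearer the other site, 78.3% on mandibular 2 and 100% on tibial 3 against 13 to 26.1% on the other arrays, restates the pattern and does not test its cause. An exchange of these arrays or their cultures, separate errors in each, and untested differences between animals all stay open.

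Macrophage and monocyte genes passed as lower in cultures labelled mandibular only in the test with the preset correlation, with adjusted p = 0.703 with an estimated correlation, 0.793 with fry and an exact permutation p of 0.2, and tibial 3 (5.55) lay below mandibular 2 (6.28). A difference in scale left in the deposited values is argued against, since array medians lay between 5.63 and 5.71. The list median was -2.11 with each array centred on its median and -2.15 after a further quantile normalization. Housekeeping genes differed by -0.0257 in the median (SD over genes 0.175). RMA had already made the distributions of the arrays equal, so none of these values tests the scaling within RMA. Cells of the monocyte and macrophage line in some cultures are a candidate explanation that stays open, since the finding that 22 of 24 genes (91.7%) had their highest levels on tibial 1 and tibial 2 restates the list means seen before it, over genes that move together. No member is in another list fixed here, but 10 of the 24 had a mandibular mean above the median of all probe sets, and CD86 stands against a uniform rise. Whether the cells differ by site, by animal or by culture stays open and untested, and the labels name no step other than plating that would remove them.

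Cell cycle genes passed as higher in cultures labelled mandibular only in the test with the preset correlation, with adjusted p = 0.703 with an estimated correlation, 0.793 with fry and an exact permutation p of 0.3, and tibial 3 (7.81) lay above mandibular 1 and 2 (7.28 and 7.31). Dilution of stromal RNA by other cells in the tibial cultures is argued against as the whole cause, since collagen and matrix genes differed by -0.0819 in the median (SD over genes 0.466) where dilution would raise them with the cell cycle genes. With the macrophage list mean as a covariate the cell cycle median was -0.20, but mandibular 1 and 3, with macrophage list means of 5.07 and 5.06, had cell cycle list means of 7.28 and 8.16. A difference in growth between cultures, animals or sites stays open and was not tested.

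The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The labelled sites gave 0 probe sets past the adjusted threshold, a count that any split reaches, with 178 as the highest of the others. They gave 836 at an unadjusted p under 0.05, which 7 of the 10 splits reached, with 3532 as the highest of the others. They gave 7 gene lists, which 4 of the 10 splits reached, with 13 as the highest of the others. All of these highest counts came from the split that puts the arrays labelled mandibular 1, mandibular 3 and tibial 3 on a side, the grouping already seen on the first principal component, which points to a structure of the samples. It is the split that the ALX1, LHX8 and HOXA7 levels follow.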
